A study of Mus musculus with 9 samples.

How the data were processed

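RNA sequencing was carried out on C2C12 cells, an established mouse myoblast line whose cells leave the cell cycle and fuse into multinucleated muscle fibres when serum is low. Per the labels, differentiation took place in DMEM with 2% fetal bovine serum, and the time given is day 3. The 9 libraries form 3 groups of 3. Control fibres stayed in normal medium. The 1C-MIM group received a One-Carbon Metabolite Induced Medium, which adds 6 metabolites of the one-carbon network. The scramble group received 6 metabolites from outside that network. The names and doses of the metabolites are not given in the sources used here. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

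Per the labels' protocols, RNA was isolated with a column kit (RNeasy) and 1.3 µg of total RNA entered each library, which was made with a SMARTer mRNA-seq kit. The submitters' processing notes name Trim Galore 0.6.7, Salmon 1.5.2, STAR, SAMtools 1.15.1, Picard 2.27.4, StringTie 2.2.1, bedtools 2.30.0, featureCounts, Subread 2.0.1, DESeq2 1.28.0 and the genome build GRCm39, without roles or order. Which tool made which value, and whether counting used strand, is not given in the sources used here. Per the file headers, the deposited tables hold a count, an FPKM and a TPM for each of 33984 RefSeq transcripts, under 24063 gene symbols. The authors' counts are whole numbers and are not normalized. The authors' FPKM values are scaled by transcript length and by the library's count total, and served here only to recover transcript lengths for a check of length bias. The authors' TPM values sum to the same total in each library and were not tested here.

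Of the symbols, 5261 (21.9%) had more than 1 transcript, and reads in exons that transcripts share were counted under each of them. Each gene was therefore represented by the transcript with the highest mean count over all 9 libraries. This choice was made after the tables had been seen, and the mean over a gene's transcripts was tried as an alternative. With 1 transcript per gene the count totals were 29.0 to 33.2 M per library, against 47.7 to 54.9 M over all transcripts. Genes that did not pass edgeR's filterByExpr were left out, which kept 14006 genes. The 10057 untested genes held 0.0280% of the counts. No mitochondrially encoded gene was among the symbols.

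Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM normalization, robust fits, all 9 libraries in 1 fit and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p below 0.05. Levels are in CPM, which scale the counts to the normalized library size, given as mean ± SD over 3 libraries, and fold changes are log2 values ± SE from the edgeR fit. TMM factors were 0.981 to 0.983 in 1C-MIM, 1.009 to 1.019 in control and 1.003 to 1.007 in scramble. The common biological coefficient of variation was 0.0842. Gene lists were tested with limma's camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the 37 of 39 lists that had at least 5 tested members. Camera asks whether a list moved relative to the other genes. List members were also adjusted over the list alone.

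The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the 2 groups, leaving out predicted genes, pseudogenes and near-identical families. Where no gene was called, the 10 smallest p stand as values only. For each list, up to 4 members with the smallest p may be named, and any member of the folate and methionine lists. Alternatives were other scalings (RLE, upper quartile, library size alone), other filters, DESeq2 1.42.0, limma-voom, the compared groups alone, the replicate number as a block, each library left out in turn, an adjusted p below 0.01, a minimum fold, another prior count and an estimated inter-gene correlation. Added after the data were seen were the removal of the libraries numbered 1, the removal of Rn45s and the mean over transcripts.

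The edgeR and camera steps were tested on simulated data. Counts were simulated for 1C-MIM against control, with 200 of 13856 genes changed. There edgeR recovered 16% of genes changed 1.25-fold, 74% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, with 9 false calls among 148. Differences below about 1.5-fold can therefore go uncalled at this depth and number of libraries where few genes change. These shares do not describe the real comparison of 1C-MIM with control. There 6621 genes were called, with a median absolute log2 fold change of 0.42. Libraries of 1 group differed by more than sampling noise in every pair (chi-square per degree of freedom 3.30 to 48.1), so none was merged. Libraries with the same replicate number were checked for shared deviations from their group means, since the labels do not say that a number marks a batch. For scramble and control every same-number pair correlated above 0.1 (0.481, 0.214 and 0.168). So did control replicate 3 with scramble replicate 2 (0.242) and control replicate 2 with scramble replicate 3 (0.123). The libraries numbered 1 may thus be paired, but for replicates 2 and 3 pairing by number cannot be told from these correlations. The values given come from the fit without the block, as fixed beforehand, and blocked values stand beside them where a call changed. For 1C-MIM with either group not every same-number pair correlated above 0.1. Rn45s, the ribosomal RNA precursor, held 0.454% of the counts in control replicate 2 and 0.148% to 0.187% in the other libraries. Exon overlaps were looked up in GENCODE vM21 (GRCm38). Since the deposited values use GRCm39, only names of overlapping genes were taken from it and no coordinates are given. Of the 129 genes that the rule allowed to be named, 43 had exons overlapping another gene and 19 a protein-coding gene.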

Results

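The series holds 9 RNA sequencing libraries from differentiated C2C12 muscle fibres: 3 from normal medium (control), 3 from medium with 6 one-carbon metabolites (1C-MIM) and 3 from medium with 6 unrelated metabolites (scramble). Depth, as total counts with 1 transcript per gene, was 31.2, 32.0 and 33.2 M in control replicates 1 to 3, 29.0, 29.5 and 30.3 M in 1C-MIM, and 31.8, 29.1 and 29.4 M in scramble. The first principal component of log2 CPM carried 66.7% of the variance and set the 3 1C-MIM libraries (scores 39.9 to 46.7) apart from the other 6 (-24.8 to -18.7). On the second component, with 11.4% of the variance, the library numbered 1 had the highest score of its group, at 27.8 in control, 7.17 in 1C-MIM and 12.9 in scramble. Control replicate 1 differed from the mean of control replicates 2 and 3 in several gene groups fixed beforehand: the median log2 difference was 0.97 for sarcomere genes, 0.45 for myogenic regulators, -0.41 for mitosis genes and -0.36 for cytosolic ribosomal proteins. Myh3, the embryonic myosin heavy chain, picked as an example after the data were seen, stood at 1738 CPM in control replicate 1 and at 753 and 608 CPM in replicates 2 and 3.

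**Figure D1:**
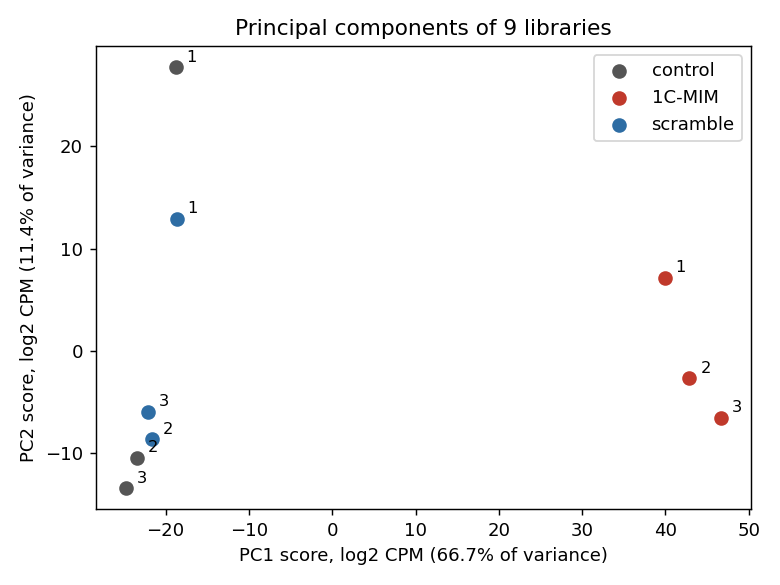
Scores of the 9 libraries on the first and second principal components of log2 CPM, coloured by group and marked with the replicate number. The 1C-MIM libraries lie between 39.9 and 46.7 on the first component and the other 6 between -24.8 and -18.7, while control replicate 1 has the highest score, 27.8, on the second.

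The comparison of 1C-MIM with control asks what the one-carbon metabolites changed in these fibres. Fibres in 1C-MIM had over 10 times more RNA of some genes. Cdkn1c, a cyclin-dependent kinase inhibitor, rose from 6.86 ± 0.11 to 84.1 ± 12 CPM (log2 fold change 3.62 ± 0.11, adjusted p = 5.9e-08). Mest, an imprinted gene of mesoderm, rose from 31.0 ± 1.7 to 331 ± 24 CPM (3.42 ± 0.17, adjusted p = 2.0e-06). The keratin gene Krt19, the neurofilament genes Nefl and Nefm, the connexin gene Gja5 and the slow myosin light chain gene Myl2 fell, and all 40 mitosis genes tested were lower.

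In total 6621 of 14006 genes were called between 1C-MIM and control (47.3%), 3212 higher and 3409 lower with 1C-MIM. Of these, 999 differed by at least 2-fold, 397 higher and 602 lower. The 3 libraries of each group did not overlap for 55.5% of genes, where chance gives 10%. Counts of called members in the lists below stand against the 47.3% called over all genes. The largest rise was in Angptl7, which encodes a secreted angiopoietin-like protein, from a mean of 0.268 ± 0.14 CPM in control to 16.6, 37.8 and 53.7 CPM in the 1C-MIM libraries (log2 fold change 7.06 ± 0.62, adjusted p = 8.2e-05). Tnfsf11, the cytokine RANKL, rose by 5.41 ± 0.48 on the log2 scale, Npy1r, a neuropeptide Y receptor, by 4.25 ± 0.56, and the circadian transcription factor Hlf by 4.01 ± 0.24. Stc1, a secreted glycoprotein hormone, rose by 5.38 ± 1.01 (adjusted p = 0.0042), with 5.95, 21.7 and 64.6 CPM in the 3 1C-MIM libraries. Sema3g (3.96 ± 0.17), the protease precursor Ctrb1 (3.46 ± 0.29) and the matrix proteoglycan Lum (3.35 ± 0.13) completed the 10 largest rises.

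The largest fall was in Gja5, which encodes connexin 40, from 19.5 ± 12 to 1.40 ± 0.26 CPM (log2 fold change -3.79 ± 0.57, adjusted p = 0.0013), with 33.1 CPM in control replicate 1 and 13.7 and 11.5 CPM in the other controls. Inmt, an enzyme that transfers methyl groups to indoles, followed with -3.10 ± 0.58. The genes Sprr1a (-2.90), the keratin gene Krt19 (-2.82) and the neurofilament genes Nefl (-2.73) and Nefm (-2.66) fell, and so did Stmn2, a tubulin-binding protein of neurons, from 105 ± 19 to 17.8 ± 2.1 CPM (-2.56 ± 0.14). Gpr35 (-2.63), Acsbg1 (-2.46) and Myl2 (162 ± 23 to 31.2 ± 2.3 CPM, -2.37 ± 0.10) completed the 10. Some named genes share exon sequence with a protein-coding gene on the opposite strand: Nefl with Nefm, Mest with Copg2, Gja5 with Gpr89, Myl2 with Ccdc63, Pfkp with Pitrm1, Csad with Zfp740, Gins2 with Gse1, Ndufs3 with Kbtbd4, Ctsb with Fdft1, Cdc25c with Gm3550 and Ccnd1 with LTO1. Igf2 and Setd1a share it with Gm49394 and Gm49388 on the same strand. Since strand use in counting is not given in the sources used here, their values are uncertain to that extent.

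**Figure D2:**
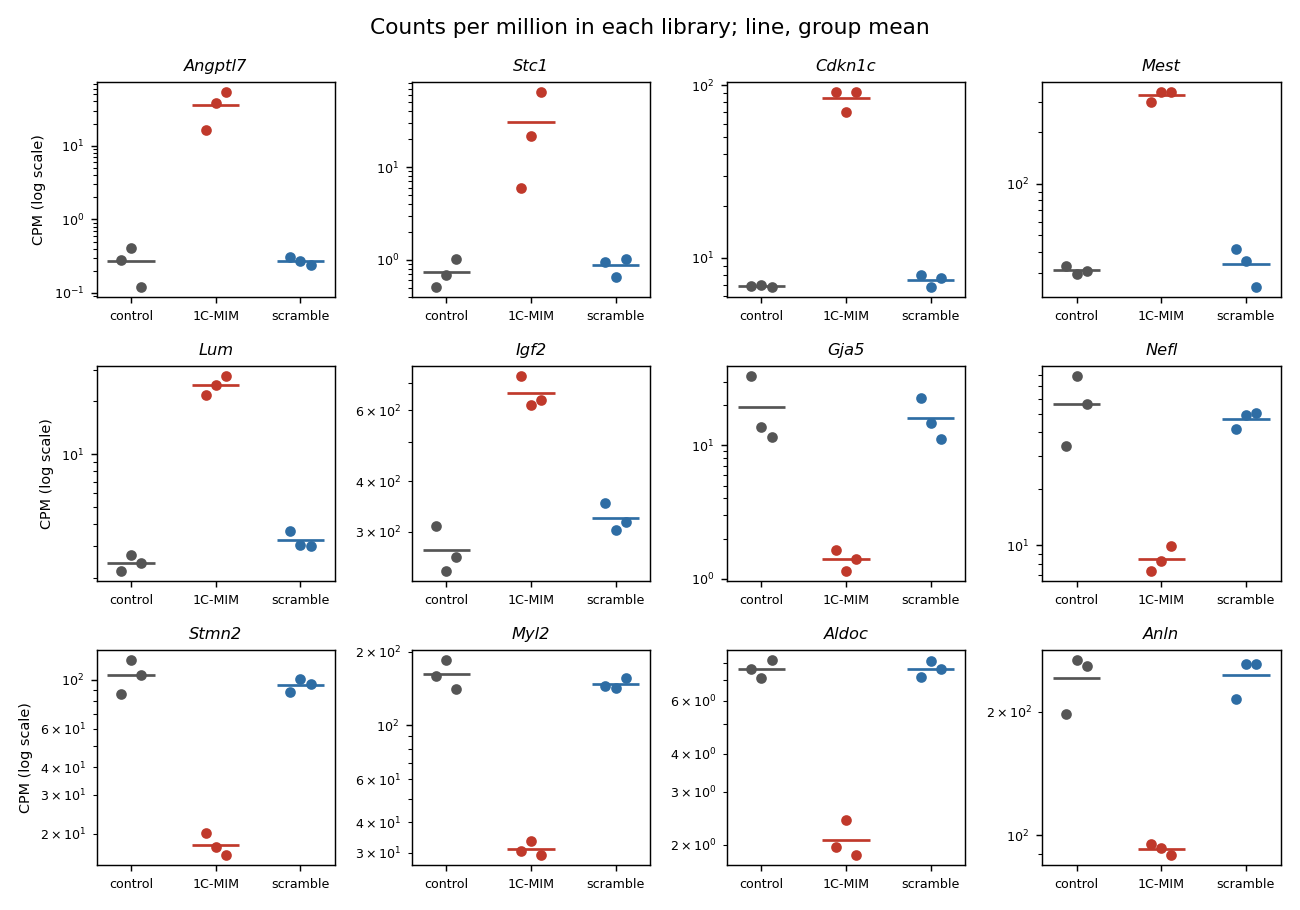
CPM (log scale) of 12 genes in each of the 9 libraries. Points are libraries and lines are means of 3 libraries. In each panel the 1C-MIM points lie on 1 side of the control and scramble points, above them for Cdkn1c (84.1 against 6.86 and 7.49 CPM) and below them for Myl2 (31.2 against 162 and 148 CPM).

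Genes of cell division were lower with 1C-MIM. All 40 mitosis genes tested fell, with a median log2 fold change of -1.08 (camera adjusted p = 2.1e-15; adjusted p = 0.703 with an estimated correlation). Anln, which organises the cleavage furrow, fell from 242 ± 38 to 92.4 ± 2.8 CPM, and the kinetochore motor gene Cenpe (-1.23), the phosphatase gene Cdc25c (-1.35) and the separase gene Espl1 (-1.10) fell with it. Of 40 DNA replication genes, 28 fell and 1 rose (median -0.39, camera adjusted p = 0.00017; adjusted p = 0.703 with an estimated correlation), among them Gins2 (-0.83), Prim1 (-0.77) and Pole (-0.67). Adjusted over the list alone the counts were 40 lower for mitosis, and 28 lower and 1 higher for replication. Control replicate 1 was itself lower in mitosis genes than the other 2 controls (median -0.41), and without it the mitosis median was -1.20. Cyclin D1, encoded by Ccnd1, fell from 174 ± 28 to 61.8 ± 4.9 CPM.

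Targets of the hypoxia response and enzymes of glycolysis were also lower. Of 21 hypoxia targets 19 fell and 0 rose (median -0.67, camera adjusted p = 1.2e-07; adjusted p = 0.674 with an estimated correlation). Pdk1, a kinase that restrains pyruvate dehydrogenase, fell from 209 ± 9.4 to 75.7 ± 5.8 CPM, Bnip3, a mitophagy receptor, from 203 ± 21 to 64.2 ± 2.8 CPM, and Ndrg1 from 200.3 ± 29 to 77.2 ± 2.6 CPM. Of 31 glycolysis genes 21 fell and 0 rose (median -0.43, camera adjusted p = 3.0e-05; adjusted p = 0.347 with an estimated correlation), including Pfkp (-1.02), Pfkl (-1.01), Gpi1 (-0.88) and Aldoc (-1.88). Adjusted over the list alone the counts were again 19 and 21. Among 75 nuclear-encoded respiratory chain genes 27 rose and 3 fell, and 26 and 3 adjusted over the list alone (median 0.11, camera adjusted p = 0.0010; adjusted p = 0.707 with an estimated correlation), with Cyc1 at 0.47, Atp5e at 0.39 and Ndufs3 at 0.37. Without control replicate 1 the respiratory chain list was no longer called (median 0.05, camera adjusted p = 0.103). Without the 3 libraries numbered 1, 32 respiratory chain genes rose and 6 fell, and 3 glycolysis genes rose while 20 fell.

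Myogenic regulators and fusion genes rose as a list, while sarcomere genes did not move as 1 group. Of 27 regulators and fusion genes 14 rose and 2 fell, also adjusted over the list alone (median 0.50, camera adjusted p = 0.00086; adjusted p = 0.703 with an estimated correlation). Igf2, a growth factor of muscle differentiation, rose from 270 ± 37 to 663 ± 59 CPM (1.30 ± 0.10), and the adhesion gene Jam2 fell by 0.63. Cdkn1c (3.62 ± 0.11), described above, is also a member and counts among the 14. The list's rise does not show that each transcription factor in it rose. The regulators were also higher in control replicate 1 than in the other 2 controls (median 0.45), and without the 3 libraries numbered 1, 20 rose and 3 fell. Of 52 sarcomere and contraction genes 4 rose, 8 fell and 40 were not called (4 and 7 adjusted over the list alone; median -0.12, camera adjusted p = 0.750). The falls included Myl2, Csrp3 (58.2 ± 5.3 to 18.8 ± 2.2 CPM), Myl4 (-0.89) and Smpx (-0.72). This median rested on control replicate 1, in which sarcomere genes were higher by 0.97: without that library it was 0.22, with 14 genes higher and 8 lower, and without the 3 libraries numbered 1 it was 0.17, with 26 higher and 10 lower. Without control replicate 3 it was -0.28, with 3 higher and 13 lower, and it was -0.24, -0.19, -0.07 and -0.04 without control replicate 2 and 1C-MIM replicates 1, 2 and 3.

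Markers of myoblasts and reserve cells went both ways: 9 of 21 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.276). The receptors Notch3 (201 ± 3.6 to 428 ± 35 CPM) and Notch1 (0.97) and the adhesion molecule Vcam1 (0.92) rose, while Cd34 fell from 123 ± 12 to 48.1 ± 4.5 CPM. Of the atrophy list 7 of 20 rose and 6 fell (camera adjusted p = 0.714), with the ubiquitin ligase gene Fbxo32 higher by 0.66. The median of that list was 0.08 and its mean -0.02, and the atrophy counts were the same adjusted over the list alone. Without the 3 libraries numbered 1, 11 rose and 6 fell (median 0.19).

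Ribosome biogenesis genes rose and some ribosomal protein genes fell. Of 33 ribosome biogenesis and MYC targets 26 rose and 1 fell, also adjusted over the list alone (median 0.29, camera adjusted p = 1.0e-06; adjusted p = 0.674 with an estimated correlation), among them Nop2 (0.76), Nolc1 (0.51) and Nop16 (0.43). Of 64 cytosolic ribosomal protein genes 8 fell and 0 rose, and 4 fell adjusted over the list alone (median -0.14, camera adjusted p = 0.027; adjusted p = 0.810 with an estimated correlation), with Rpl3 at -0.55, Rps20 at -0.56 and Rpl10a at -0.45. Over all tested genes 3409 of 14006 fell, a larger share than these 8 of 64. The ribosomal protein genes were lower in control replicate 1 than in the other 2 controls (median -0.36). Without control replicate 1, 51 of the 64 were lower, and without the 3 libraries numbered 1, 62 were lower. Leaving out control replicate 2, control replicate 3 or 1C-MIM replicate 1 left 4 lower in each case and ended the list's call (camera adjusted p = 0.257, 0.275 and 0.119). With library size alone as the scale, 14 were lower.

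Inflammatory, p53, lysosomal and matrix lists were higher with 1C-MIM. Of 24 inflammatory cytokines and NF-kappaB targets 17 rose and 2 fell (median 0.45, camera adjusted p = 0.00021; adjusted p = 0.347 with an estimated correlation). The chemokines Cxcl1 (10.2 ± 1.0 to 43.9 ± 9.9 CPM) and Cxcl5 (75.1 ± 3.9 to 296 ± 68 CPM) rose, and Il34 fell by 0.98. Of 23 p53 targets 13 rose and 4 fell (median 0.29, camera adjusted p = 0.027; adjusted p = 0.674 with an estimated correlation), among them Zmat3 (1.12), Trp53inp1 (1.10), Aen (0.67) and Ccng1 (0.59). Of 34 lysosome and autophagy genes 14 rose and 3 fell (median 0.15, camera adjusted p = 0.032; adjusted p = 0.703 with an estimated correlation). Map1lc3a, an autophagosome protein, rose from 179.6 ± 11 to 360.2 ± 4.5 CPM and Ctsb rose by 0.57. The lysosome call was lost without control replicate 2, control replicate 3 or 1C-MIM replicate 2 (camera adjusted p = 0.0543, 0.0913 and 0.0501). Of 47 collagen and matrix genes 23 rose and 10 fell (median 0.21, camera adjusted p = 0.0064; adjusted p = 0.674 with an estimated correlation). Lum, Dcn (197 ± 5.6 to 438 ± 3.7 CPM), the collagenase gene Mmp2 (1.46 ± 0.07) and Lamb1 (1.12 ± 0.06) rose most clearly, and without the 3 libraries numbered 1 the list had a camera adjusted p of 0.0705. Without 1C-MIM replicate 1 the matrix median was 0.12. Adjusted over the list alone, the counts of these 4 lists were the same.

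Genes of the one-carbon network itself moved in both directions, as did genes at large. Of 25 folate cycle genes 9 rose and 4 fell (camera adjusted p = 0.473), and of 18 methionine cycle and transsulfuration genes 4 rose and 6 fell (camera adjusted p = 0.714), with the same counts adjusted over the list alone. Over all 14006 tested genes 47.3% were called, 3212 higher and 3409 lower. Neither list was called relative to the other genes. Mtr, methionine synthase, rose from 29.6 ± 1.2 to 52.7 ± 3.1 CPM (0.83 ± 0.06, adjusted p = 2.4e-06), and Mtrr, which reactivates it, rose by 0.39. Mthfd1l, a mitochondrial enzyme that releases formate, fell from 94.6 ± 17 to 49.5 ± 2.4 CPM (-0.94 ± 0.11), and Mthfd2l fell by 0.54. Mat2a, which makes S-adenosylmethionine, fell from 237 ± 12 to 173 ± 3.7 CPM (-0.46 ± 0.05), Csad, of taurine synthesis, fell by 0.82 and Gclm, of glutathione synthesis, by 0.49. Gamt, which uses S-adenosylmethionine to make creatine, rose by 0.69, and the transsulfuration enzymes Cbs and Cth rose by 0.94 and 0.96 from levels of 2.49 and 2.14 CPM.

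Lists around the network were not called either. Of 17 polyamine and methionine salvage genes 6 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.452), with Azin1, an antizyme inhibitor, falling from 226 ± 21 to 111 ± 4.3 CPM while Amd1 rose by 0.57 and Mri1 by 0.80. Of 37 serine synthesis and ATF4 targets 11 rose and 10 fell (camera adjusted p = 0.750), with the hormone gene Fgf21 higher by 1.73, Slc3a2 higher by 0.63 and Nupr1 lower (-0.89). The ATF4 median was -0.01, with a mean of 0.07 and the camera direction up. Of 36 genes of DNA and histone methylation 10 rose and 4 fell (camera adjusted p = 0.452), including Kmt2d (0.63), Setd1a (0.25), Kdm3a (-0.68) and Uhrf1 (-0.77). Without the 3 libraries numbered 1, 14 rose and 8 fell. This list holds demethylases such as Kdm3a beside enzymes that add methyl groups, so its counts give no direction of methylation. Of 22 purine and pyrimidine synthesis genes 3 rose and 11 fell (camera adjusted p = 0.194), with Ctps at 0.38 and Rrm2 at -0.83. Adjusted over the list alone, the counts of these last 3 lists were the same.

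The comparison of 1C-MIM with scramble sets the one-carbon metabolites against the same number of unrelated ones. It gave much the same picture as the comparison with normal medium. Cdkn1c stood at 84.1 ± 12 CPM with 1C-MIM and 7.49 ± 0.62 CPM with scramble (log2 fold change 3.49 ± 0.11, adjusted p = 8.3e-08), and Mest at 331 ± 24 and 33.8 ± 8.5 CPM (3.29 ± 0.17). All 40 mitosis genes, 17 of 21 hypoxia targets and 21 of 31 glycolysis genes were lower, and of 27 myogenic regulators 14 were higher and 3 lower. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.693 with an estimated correlation, and 0.327 for glycolysis). Of 14006 genes, 6449 were called (3202 higher and 3247 lower with 1C-MIM), 942 of them by at least 2-fold (394 higher and 548 lower), and the groups did not overlap for 59.5% of genes, where chance gives 10%. Called against both control and scramble were 5724 genes, 2809 higher and 2915 lower, all in the same direction in both. These comparisons share the 1C-MIM libraries, so their fold changes are not independent (Pearson r = 0.959 across genes, which are not independent replicates).

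The largest differences from scramble were again Angptl7 (7.01 ± 0.62), Stc1 (5.14 ± 1.00), Tnfsf11 (5.03 ± 0.47), Npy1r (4.34 ± 0.57), Hlf (3.95 ± 0.24), Sema3g (3.76 ± 0.17), Ctrb1 (3.36 ± 0.29) and Lum (2.92 ± 0.12) on the higher side. On the lower side stood Inmt (-3.79 ± 0.57), Gja5 (-3.52 ± 0.57), Sprr1a (-2.72), Nefm (-2.63), Krt19 (-2.56), Gpr35 (-2.55), Nefl (-2.46), Stmn2 (-2.42), the collagen gene Col8a2 (18.7 ± 3.6 to 3.59 ± 1.5 CPM, -2.38 ± 0.27) and Acsbg1 (-2.30). Mtr rose by 0.89 and Cth by 1.20, while Mthfd1l fell by 0.85 and Csad by 0.89. Of 25 folate cycle genes 10 rose and 4 fell, and of 18 methionine cycle genes 4 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.337 and 0.849). Over all 14006 tested genes 3202 rose and 3247 fell in this comparison. The methionine median was -0.07, with a mean of 0.03 and the camera direction down.

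Of the 37 lists 11 were called between 1C-MIM and scramble. All 40 mitosis genes fell (median -1.11, camera adjusted p = 1.9e-16), among them Anln (-1.41) and Cdc25c (-1.42), and 26 of 40 replication genes fell while 2 rose (28 and 2 adjusted over the list alone; median -0.35, camera adjusted p = 0.00028). Without 1C-MIM replicate 3, scramble replicate 2 or scramble replicate 3, the falling replication genes numbered 16, 16 and 17. Of 21 hypoxia targets 17 fell (median -0.58, camera adjusted p = 1.6e-07), including Car9, a carbonic anhydrase (128 ± 22 to 38.2 ± 4.2 CPM), Pdk1 (-1.34) and Bnip3 (-1.58). Of 31 glycolysis genes 21 fell (median -0.34, camera adjusted p = 1.9e-05), with Pfkp at -1.02 and Aldoc at -1.88. Ribosome biogenesis (25 of 33 higher and 1 lower, 27 and 1 adjusted over the list alone; camera adjusted p = 3.3e-07), inflammatory targets (18 of 24 higher and 2 lower; camera adjusted p = 0.00028) and myogenic regulators (14 of 27 higher and 3 lower; camera adjusted p = 0.0026) were higher. With an estimated correlation the adjusted p = 0.693 for mitosis, replication, hypoxia, ribosome biogenesis and myogenic regulators, and adjusted p = 0.327 for glycolysis and inflammatory targets. Adjusted over the list alone, 40 mitosis, 17 hypoxia and 21 glycolysis genes fell, 1 glycolysis gene rose, and the inflammatory and myogenic counts stayed at 18 and 2 and at 14 and 3.

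The other 4 called lists were weaker. The respiratory chain (28 of 75 higher and 3 lower, 27 and 3 adjusted over the list alone; camera adjusted p = 0.0030, and adjusted p = 0.796 with an estimated correlation) had 18 higher and 1 lower without 1C-MIM replicate 3, and lost the call without scramble replicate 1 (median 0.07, camera adjusted p = 0.0707). Without the 3 libraries numbered 1, 34 of its genes were higher and 7 lower, and 3 glycolysis genes were higher. The p53 targets (12 of 23 higher and 4 lower, also adjusted over the list alone; camera adjusted p = 0.044, and adjusted p = 0.693 with an estimated correlation), among them Zmat3 (1.06), lost it without 1C-MIM replicate 1, 1C-MIM replicate 3 or scramble replicate 3 (0.0609, 0.0506 and 0.0570), and without the 3 libraries numbered 1 (0.0551). The lysosome list (14 of 34 higher and 4 lower, also adjusted over the list alone; camera adjusted p = 0.048, and adjusted p = 0.693 with an estimated correlation), with Map1lc3a at 0.88, lost it without control replicate 1 or 2 (0.0546 each), 1C-MIM replicate 2 or 3 (0.0716 and 0.0570) or scramble replicate 3 (0.103), and also with the filter at 1 CPM. Of the cytosolic ribosomal proteins 8 of 64 were lower, 3 adjusted over the list alone (camera adjusted p = 0.042, and adjusted p = 0.879 with an estimated correlation), against 3247 of all 14006 genes, a larger share. Without control replicate 1, which enters through the shared spread, 24 were lower, without the 3 libraries numbered 1, 52 were lower, and without scramble replicate 1, 12 were lower. The list was not called without 1C-MIM replicate 1 or 2 (4 and 3 lower; 0.151 and 0.0542) or scramble replicate 2 or 3 (3 lower each; 0.211 and 0.140), and 3 were lower without 1C-MIM replicate 3. Collagen and matrix genes were not called (21 of 47 higher and 13 lower, also adjusted over the list alone; camera adjusted p = 0.166), although Dcn (0.97), Vcan (1.16) and Lamb1 (1.04) rose. Sarcomere genes had 4 higher and 7 lower of 52, also adjusted over the list alone, and 16 higher and 13 lower without the 3 libraries numbered 1. Their median was 0.03, their mean -0.11 and the camera direction down (adjusted p = 0.784), and the median was -0.03, -0.11 and -0.07 without 1C-MIM replicate 1, scramble replicate 2 and scramble replicate 3, and below 0 with library size alone. Without control replicate 1, 9 were higher and 12 lower.

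**Figure D3:**
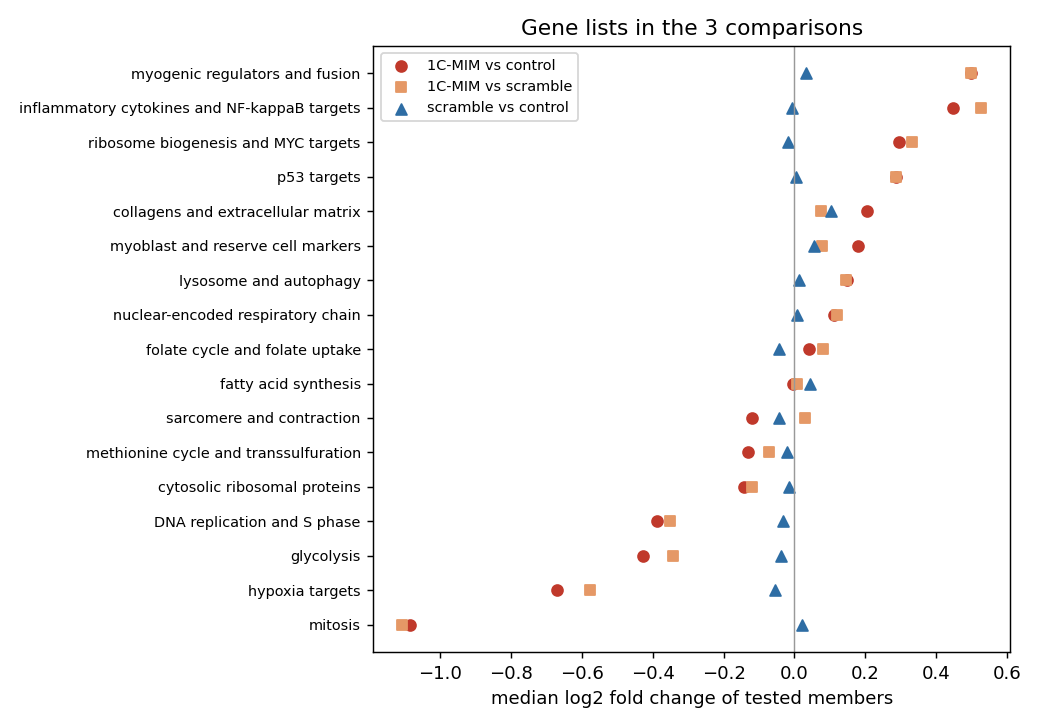
Median log2 fold change of the tested members of 17 gene lists in the 3 comparisons. Points for 1C-MIM against control and against scramble reach from the mitosis medians (-1.08 and -1.11) to the myogenic median against control (0.50) and the inflammatory median against scramble (0.53), while the scramble points lie near 0, with 0.10 for collagens and extracellular matrix.

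The comparison of scramble with control asks what adding metabolites as such does. No single gene was called by edgeR, and the gene groups that differed did so by small amounts. Collagen and matrix genes were slightly higher with scramble as a list (median log2 fold change 0.10 over 47 genes, camera adjusted p = 1.4e-12; adjusted p = 0.203 with an estimated correlation). Fatty acid synthesis genes were likewise higher (median 0.04 over 19 genes, camera adjusted p = 0.014; adjusted p = 0.774 with an estimated correlation). In both lists 0 members were called, also adjusted over the list alone, while without the 3 libraries numbered 1, 5 matrix and 2 fatty acid synthesis genes were higher.

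Of 14006 genes, edgeR called 0 between scramble and control, 482 had an unadjusted p below 0.05 (3.44%; 690 with the replicate number as a block), limma-voom called 0, and DESeq2 called 32, all 32 higher with scramble, among the 2029 genes to which it gave an adjusted p. The groups did not overlap for 9.09% of genes, where chance gives 10% for unpaired libraries. The smallest adjusted p was 0.167, for Omd, a matrix keratan sulphate proteoglycan, at 56.9 ± 2.4 CPM with scramble and 42.1 ± 1.3 CPM in control (0.43 ± 0.06). The next smallest p belonged to the extracellular sulphatase gene Sulf2 (0.30 ± 0.06), which overlaps Ncoa3 on the opposite strand, Olfml2b (0.26 ± 0.05), the fibulin genes Fbln7 (0.36 ± 0.08) and Fbln1 (0.35 ± 0.08), Trib3 (-0.46 ± 0.10), Trmt10a (-0.30 ± 0.07; overlapping Mttp on the opposite strand), Ip6k2 (-0.23 ± 0.05), Enpp3 (0.26 ± 0.06) and Hpgd (-0.33 ± 0.08), each with an adjusted p of 1.00. Of the matrix list, Dcn was at 0.18, Mmp2 at 0.22 and Lum at 0.43, and of the fatty acid synthesis list Fads1 was at 0.16, Scd1 at 0.19 and Fads2 at 0.19, none of them called.

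The libraries numbered 1 weighed on this comparison. Without control replicate 1 edgeR called 3 genes, and without the 3 libraries numbered 1 it called 96, 81 higher and 15 lower with scramble. Genes at an unadjusted p below 0.05 numbered 482 of 14006 with all libraries and 1254 of 14123 without control replicate 1. They numbered 1375 of 14020 without the 3 libraries numbered 1, and 335 to 524 with any other single library left out. The number of lists called rose from 2 to 11 without control replicate 1, 7 without control replicate 2, 6 without control replicate 3, 5 without scramble replicate 1 and 5 without scramble replicate 3. Sarcomere genes had a median of -0.04 with all libraries (mean -0.06, camera direction up, adjusted p = 0.925) and 0.33 without control replicate 1 (camera adjusted p = 2.4e-09), and -0.19 without control replicate 3 (0.00024). With the replicate number as a block, the myogenic regulators were called as well (camera adjusted p = 0.030 against 0.155 without the block; adjusted p = 0.942 with an estimated correlation). The matrix list stayed called with each library left out. The fatty acid synthesis list was lost without control replicate 3 or scramble replicate 1 (0.0847 and 0.0634).

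Fold changes of 1C-MIM and of scramble against control were correlated across the 14006 genes, which are not independent replicates (Pearson r = 0.213). Both use the same 3 control libraries, so a positive value arises with no effect at all: in 100 simulations of unchanged groups r was 0.491 on average (0.467 to 0.515). The covariance was 0.0181, against 0.0143 simulated (upper limit of the simulations 0.0153), a difference of 0.0038. Without control replicate 1 r was 0.346 and the covariance 0.0393, and without scramble replicate 1 r was 0.141. The simulations kept all 3 controls, and fewer shared controls raise the covariance that arises with no effect. They therefore give no matching value for these removals. The simulations treat the libraries as independent, while the libraries numbered 1 deviated from their groups together (correlation of deviations 0.153 to 0.481), so the difference is not an estimate of a shared effect alone. The simulations also use 1 spread per gene for all groups, while the control libraries differed more from each other. Within groups, chi-square per degree of freedom was 7.70 to 48.1 in control, 3.30 to 15.8 in scramble and 4.24 to 13.5 in 1C-MIM. The simulated covariance may thus be too low. The 3 controls cannot be split into parts of 2 libraries each, and part or all of the excess may come from the shared controls. The SD of the fold changes was 0.56 for 1C-MIM and 0.15 for scramble.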

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

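The removal of the libraries numbered 1, the removal of Rn45s and the mean over transcripts were tests chosen after the results were seen. All 161 called gene results checked kept their direction and call under every alternative run for them (RLE factors, no filter, DESeq2, limma-voom, replicate block, each library left out, libraries numbered 1 left out). Most had been picked for a large change or a small p, which favours this. Over all genes, 5391 of the 6621 calls against control stayed without 1C-MIM replicate 3. Against scramble 5188 of 6449 stayed without scramble replicate 2. These were the lowest with 1 library left out. For 1C-MIM against control and against scramble, edgeR called 999 and 942 genes with a log2 fold change of at least 1, against 6621 and 6449 without that limit, as fewer genes can pass. All other alternatives stayed within 1.5 times, and with 1 library left out the counts were 5487 to 7195 and 5267 to 7473. With library size alone the share of higher calls was 39.7% and 42.9%, against 48.5% and 49.7% with TMM. For scramble against control, DESeq2 called 32 genes, edgeR without the libraries numbered 1 called 96, and edgeR with 1 library left out called 0 to 3; the cause was not tested. With a correlation estimated per list, 0 lists were called in each of the 3 comparisons, against 12, 2 and 11; the cause was not tested. For scramble against control the list count was 2 to 11 with 1 library left out and 10 without the libraries numbered 1; the cause was not tested. For 1C-MIM the list counts with 1 library left out were 10 to 12 against control and 8 to 11 against scramble. The replicate number as a block gave 7397, 0 and 7309 genes, 12, 3 and 11 lists, and r = 0.205 for the correlation of the fold changes. The block added the myogenic list for scramble against control and changed no other call of a named gene or called list. Same-number deviations correlated above 0.1 in 6 of 9 pairs (0.0279 to 0.481), including all 3 of scramble with control and all 3 numbered 1. Control and scramble replicates 2 and 3 of unlike number correlated as well (0.242 and 0.123), so pairing by number is not shown for them. The correlation of 0.213 ranged from 0.141 to 0.346 with 1 library left out. The removal of mitochondrially encoded genes was not run, since no such symbol is present. At totals of 29.0 to 33.2 M counts the simulation, with 200 changed genes, recovered 74% of genes changed 1.5-fold. Smaller differences can go uncalled where few genes are called, as for scramble against control.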

Other observations

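The tests on the share of differentiated and undifferentiated cells and on the number of calls with library size alone were chosen after the results were seen, and the list of imprinted genes was written after 5 of them had been seen to be higher. In several gene groups not described above single genes changed with 1C-MIM against control, as did 47.3% of all tested genes, while no group was called. Neural marker genes, which C2C12 fibres express in part, had 3 of 7 lower and 0 higher (also adjusted over the list alone; camera adjusted p = 0.276): Nefl, Nefm and Tubb3, a neuronal tubulin, which fell from 70.0 ± 17 to 21.2 ± 1.6 CPM. Of 9 osteoblast and chondrocyte markers 1 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.439), with Bglap2, an osteocalcin gene, falling from 17.7 ± 3.9 to 5.01 ± 0.84 CPM and the endopeptidase gene Phex rising from 23.3 ± 3.0 to 70.2 ± 10 CPM; without the libraries numbered 1, 2 rose and 3 fell. Of 13 smooth muscle and fibroblast markers 6 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.454), with Pdgfra at 0.84, Pi16 at 1.67 and Cd248 at -1.10. Of 26 genes of a Wnt list, which holds ligands such as Wnt10b and other pathway genes beside targets, 7 rose and 6 fell. The counts were the same adjusted over the list alone (camera adjusted p = 0.547), with Wnt10b at -2.07 and Ccnd1 at -1.49.

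Lipid and stress genes were mixed. Of 33 fatty acid oxidation genes 7 rose and 10 fell (7 and 11 adjusted over the list alone; camera adjusted p = 0.547), with lipoprotein lipase, Lpl, rising from 196 ± 7.6 to 548 ± 139 CPM, Acaa2 at -0.64 and the fatty acid transporter Cd36 at -1.08. Of 25 cholesterol synthesis genes 2 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.208), with Hmgcs1 at -0.49 and Fdft1 at 0.41; without the 3 libraries numbered 1, 14 fell. Of 31 genes of the TCA cycle and pyruvate dehydrogenase 11 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.246), with pyruvate carboxylase, Pcx, rising from 36.4 ± 8.4 to 82.1 ± 4.4 CPM and Pdk4 at -0.98. Of 32 chaperone and unfolded protein response genes 9 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.163), with Hyou1 at 0.61, Calr at 0.69 and Hspb1 at -0.68; without the libraries numbered 1, 11 rose and 6 fell. Of 33 NRF2 and oxidative stress genes 8 rose and 12 fell, also adjusted over the list alone (camera adjusted p = 0.598), with Tkt at -0.69 and Slc7a11 at -0.83. Of 26 immediate early genes 12 rose and 8 fell (14 and 8 adjusted over the list alone; camera adjusted p = 0.325), with Klf6 at -0.72, Klf4 at -0.77 and Fosl2 at 0.57. The other lists were not called either: 4 of 19 choline, betaine and creatine genes rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.767), as did 7 and 4 of 19 fatty acid synthesis genes (7 and 4; 0.452), 10 and 8 of 20 TGF-beta and YAP targets (10 and 9; 0.598), 4 and 3 of 27 interferon-stimulated genes (1 and 1; 0.738), 1 and 1 of 7 replication-dependent histones (1 and 1; 0.964) and 1 and 0 of 5 leukocyte and endothelial markers (1 and 0; 0.452). The adipocyte list had 3 tested genes, too few for a list test, and 1 of them fell.

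With 1C-MIM against control 6621 genes were called, about as many higher as lower. On depth, 86.4% of the genes called against all 3 scramble libraries were also called against scramble replicates 2 and 3. The depth of these 2 (29.1 and 29.4 M) is close to that of the 1C-MIM libraries (29.0 to 30.3 M). Leaving out scramble replicate 2 or 3 instead kept 5188 and 5230 of the 6449 calls, against 5569 here. The share kept need not reflect depth, so it does not decide whether depth played a part. No comparison of like depth was run against control, at 31.2 to 33.2 M. Against length and GC bias, 94.9% of the 6324 calls among genes with known length and GC content were left after each library's trend with both was removed. The even split does depend on scaling: with library size alone 39.7% of the calls were higher, which passed the bound of 40% set beforehand, so the TMM factors may have made the split even. The number of calls did not, at 6569 with library size alone. The real grouping called 6621 genes against control and 6449 against scramble, with 1 of 10 splits as large in each and 0 calls in the highest other split. The other splits mix libraries of both groups in each part, which widens the spread, so few calls could arise there. For scramble against control the real count was 0 edgeR calls, so all 10 of 10 splits had to give as many. The highest of the others was 0, also among the 4 splits that part all 3 same-number pairs. In that comparison 482 genes had an unadjusted p below 0.05 (1254 without control replicate 1), DESeq2 called 32 and limma-voom 0. At 10 splits a share under 0.05 cannot arise, so these counts decide nothing.

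With 1C-MIM against control all 40 mitosis genes fell, and of 27 myogenic regulators 14 rose and 2 fell (both list calls lost, adjusted p = 0.703 with an estimated correlation), and a shift in the share of differentiated cells is a candidate explanation. A smaller share of undifferentiated cells alone was taken to lower the myoblast and reserve cell markers with the mitosis genes. The markers' median was 0.18 (95% bootstrap interval -0.14 to 0.61), above that of mitosis (-1.16 to -0.99), and this held with each compared library left out. Whether all these markers follow the share of such cells was not tested. A larger share of differentiated cells alone was taken to raise the sarcomere genes by about as much as the regulators. That premise is uncertain: control replicate 1 exceeded the other 2 controls by 0.97 in sarcomere genes and by 0.45 in regulators. The 2 lists need not move equally, so an unequal rise does not decide the question. The regulators' median exceeded the sarcomere median by 0.62 (95% bootstrap interval 0.17 to 0.85) against control, by 0.35 (0.079 to 0.65) without control replicate 1, and by 0.47 (0.098 to 0.76) against scramble. These intervals cover the spread between genes and not between libraries, but the difference, taken in each library from the mean of all 9, was 0.24 to 0.40 in the 1C-MIM libraries and -0.56 to 0.07 in the other 6. A part played by cell shares, a change in a cycling subset of these cells, and a direct effect of the metabolites on these genes, which was not tested, stay open.

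Cdkn1c, Mest, Igf2, Copg2 and Dcn, all imprinted in at least some tissues, rose with 1C-MIM against control. If imprinted genes rose as a class, the 39 other imprinted genes tested should rise too, but their camera p was 0.277 without adjustment, with the direction down. Of these 39 genes 8 rose, 14 fell and 17 were not called (median -0.15), with Igf2r at 0.81, Ddc at 1.57, H19 at -0.32 and Peg10 at -0.86. The largest rises among them were Plagl1 (2.59) and Dio3 (2.56), from 0.32 and 0.093 CPM in control. The largest falls were Slc38a4 (-2.39) and Rasgrf1 (-2.30), from 0.43 and 0.98 CPM. Camera asks for a shared direction, so it cannot speak to imprinted genes that move in opposite directions. Reads shared between overlapping genes might account for Mest and Copg2, which overlap on opposite strands, and 3 of the 5 genes overlap none of the others. That bound, set beforehand, left out genes other than these 5: Cdkn1c overlaps Gm44732, and Igf2 overlaps Gm49394 and Igf2os, so shared reads stay open for 4 of the 5, and only Dcn overlaps no other gene. Regulation of single genes by the metabolites was not tested.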
